A study of Mus musculus with 12 samples.

How the data were processed

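RNA was profiled from HSC and MPP sorted by flow cytometry from 3 Nfat5-deficient and 3 control mice, with 1 array per mouse and population. Per the labels' protocols, RNA was extracted with a Qiagen method, 300 pg per sample was amplified and biotin-labelled with NuGEN kits, and the mice were untreated. The deposited values are log2 intensities per probe set that the authors normalized between arrays with RMA, per the submitters' processing notes, which also name limma. Versions of either tool are not given in the sources used here. RMA subtracts background, sets all arrays to 1 distribution and summarises probes, so a shift of the whole transcriptome between groups would be removed and differences of weakly expressed genes are compressed. The amplification from this little RNA adds noise to weak transcripts. Scanner files and detection calls were not used here, so precision is set by the number of arrays.

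The deposited table held 22142 probe sets. The annotation of its probes gave 1 gene symbol for 19527 probe sets, several for 0 and none for 2615, which are unnamed here. The gene identifiers of those 19527 probe sets were matched to a table of the GRCm38.p6 assembly, used only for names and for which genes neighbour Nfat5. Where a gene had several probe sets (33 genes) the one with the highest mean was kept, which left 19494 genes. The 4874 genes in the lowest 25% of mean value over all 12 arrays (below 4.96) were left out, and 14620 were tested.

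The 4 groups were fitted as group means in 1 limma model (R 4.3.3, limma 3.58.1, statmod 1.5.0) over all 12 arrays, with contrasts for KO against WT in HSC and in MPP, HSC against MPP in WT and in KO, and the interaction. For the mean of both populations, the arrays of each mouse were averaged and 3 mice compared with 3. Tests were two-sided moderated tests with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene passed at an adjusted p under 0.05. Cells of 3 separate animals per genotype are the replicates. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 30 lists within a comparison, and again with an estimated correlation. The fry rotation test, which asks whether a list's genes move on balance one way, was an alternative. Members were also counted when adjusted over the list alone. This makes no adjustment across the 30 lists, so some such passes are to be expected from chance. Nfat5 was compared by a two-sided exact permutation test.

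The lists covered NFAT5 osmoadaptive targets, type I interferon-stimulated genes, interferon receptors, sensors and signal transducers, MHC class I and class II presentation, NF-kB and inflammatory cytokine genes, stem cell, lymphoid priming, myeloid progenitor and megakaryocyte and erythroid genes. They also covered DNA replication, mitosis, quiescence, p53 target, unfolded protein and integrated stress response, immediate early and heat shock, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein and reactive oxygen defence genes. Markers of B cells, T and NK cells, mature neutrophils, monocytes and macrophages, erythroid cells, endothelial and stromal cells and dendritic cells stood for other cell types that a sort can hold. The sex genes, the neighbours of Nfat5 and abundant transcripts as a sign of RNA quality completed them. Groups, tests, lists, the alternatives named below unless stated otherwise, and the rule for naming genes were fixed before the data were examined. By that rule the text names Nfat5, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap (5 each in KO for HSC against MPP, in the interaction and in the mean of both populations), and up to 4 members of each list with the lowest p. Where fewer than 5 passed in a direction in the main comparisons, up to 5 genes with the lowest unadjusted p and an absolute log2 difference of at least 0.5 were added as values that did not pass.

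HSC and MPP arrays pair by animal, as the labels give the mouse of each sample. Deviations from the group mean correlated between the arrays of a mouse with r of 0.032 to 0.091 across genes (mean 0.055), and 2 of 6 arrays correlated best with their own partner. The fit with the mouse as a block was an alternative, fixed for comparisons within mice and random for KO against WT, where its consensus correlation was 0.0723.

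Further alternatives were no filter, a filter at 50%, the mean of a gene's probe sets, a second quantile normalization, trended and robust variance moderation, array weights, only the arrays compared, and leaving out each mouse. Added after the data were seen were a fit without the HSC array of KO mouse 2 and a fit with the mean of the neutrophil markers as a covariate. Also added then were the block and the left-out mice for named list and family members, and an estimated correlation for lists under the block, without that array and, where a list was gained in HSC or in the interaction, without a mouse, with array weights or with the covariate. The overlap of HSC against MPP calls from separate fits per genotype was added then as well. The pipeline was tested on 20 simulated data sets with 200 changed genes among 14620. For KO against WT in HSC it recovered 48.2%, 83.9% and 93.0% of genes changed by 1, 2 and 3 on the log2 scale, and 47.6%, 84.0% and 94.8% in MPP. For HSC against MPP it recovered 48.1%, 84.1% and 93.5% in WT and 47.8%, 84.0% and 93.9% in KO. For the mean of both populations it recovered 53.7%, 88.5% and 95.8%, and for the interaction 18.5%, 65.6% and 84.0%. False calls averaged 37.8 per data set for KO against WT in HSC, 19.8% of calls and thus above the nominal 5%. The share of false calls was 9.72% for MPP, 7.97% for HSC against MPP in WT, 7.30% in KO, 8.57% for the interaction and 4.84% for the mean of both populations. A list shifted by 0.5 was called in 100% of data sets, and in 95% for the interaction. The simulated noise was drawn for each gene on its own, so this list recovery does not hold for genes that vary together. With 200 changed genes the adjusted threshold is looser than where few genes change, so recovery there would be lower.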

Results

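Gene expression was measured in blood-forming stem and progenitor cells sorted from the bone marrow of untreated mice. Vav-Cre removes loxP-flanked genes throughout the haematopoietic system, and the knockout animals (KO) carried loxP-flanked copies of Nfat5, the gene of a transcription factor known for the response to osmotic stress. Control animals (WT) carried intact Nfat5 and the same Cre. Haematopoietic stem cells (HSC) were taken from the lineage-negative, Sca-1 and Kit positive compartment as CD150-positive cells without CD48, and multipotent progenitors (MPP) as CD48-positive cells without CD150. Each of 3 KO and 3 WT mice gave 1 HSC and 1 MPP array, which made 12 arrays in 4 groups of 3. The number of arrays limits the precision of every value below. Array medians lay between 5.81 and 5.91 on the log2 scale. The correlation between arrays of a group, taken across genes, was 0.943 to 0.946 in WT HSC, 0.925 to 0.947 in KO HSC, 0.960 to 0.973 in WT MPP and 0.950 to 0.963 in KO MPP, against 0.910 to 0.945 between HSC and MPP arrays. The HSC array of KO mouse 2 stood apart, with deviations from its group mean that had an SD of 0.438, against 0.276 to 0.378 on the other 11 arrays.

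Nfat5 itself was lower on every KO array than on every WT array of the same population. In HSC it read 7.69 ± 0.31 in KO and 8.60 ± 0.36 in WT (SD, n = 3), a log2 difference of -0.91 that put the KO signal at 53.1% of WT. In MPP it read 7.16 ± 0.25 in KO and 8.03 ± 0.24 in WT (SD, n = 3), a log2 difference of -0.87 or 54.8% of WT. Averaged over both populations of each mouse, it read 7.43 ± 0.036 in KO and 8.32 ± 0.16 in WT mice (SD, n = 3), a log2 difference of -0.89. A two-sided exact permutation test gave p = 0.1 in each case, the smallest value that 3 against 3 allows. By limma the difference had an adjusted p of 0.566 in HSC, of 0.99991 in MPP and of 0.897 over both populations. The remaining signal cannot be read as remaining NFAT5, since the position of the probe set against the deleted part is not given in the sources used here.

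**Figure D1:**
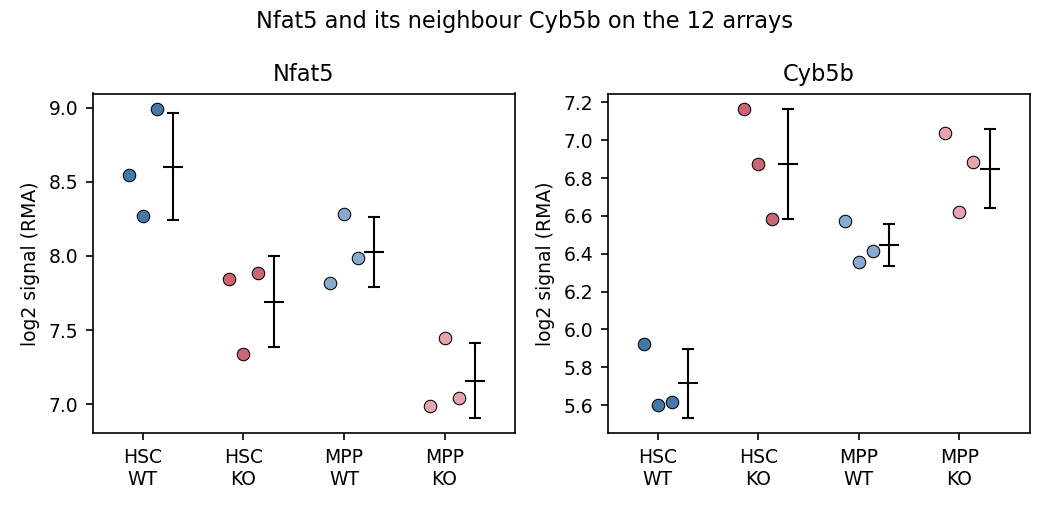
Log2 signal of Nfat5 (left) and of its neighbour Cyb5b (right) on the 12 arrays, with 1 point per array, grouped by population and genotype, and with the group mean and SD beside the points (n = 3). Nfat5 lay at 7.34 to 7.89 in KO and 8.27 to 8.99 in WT HSC, and Cyb5b at 6.58 to 7.17 in KO and no higher than 5.92 in WT HSC.

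The comparison of KO with WT HSC asked what loss of NFAT5 changes in stem cells at steady state. Among the genes with the lowest p was Cyb5b, which encodes a cytochrome b5 of the mitochondrial outer membrane and lies next to Nfat5. It read 6.87 ± 0.29 in KO and 5.71 ± 0.18 in WT HSC (SD, n = 3), a log2 difference of 1.16 (SE 0.18, adjusted p = 0.295 over all genes). Other large positive differences were those of Ino80e, a subunit of the INO80 chromatin remodelling complex, at 3.84 (SE 0.65), Fkbp5, a glucocorticoid-inducible co-chaperone of Hsp90, at 2.16 (SE 0.40), Hadh, an enzyme of mitochondrial fatty acid oxidation, at 1.99 (SE 0.34), and Capzb, an actin-capping protein, at 1.41 (SE 0.25). On the negative side stood Mms22l, a recombination factor at stalled replication forks, at -1.35 (SE 0.20), Layn, a hyaluronan receptor, at -1.30 (SE 0.20), Ttll5, a tubulin polyglutamylase, at -1.50 (SE 0.28), Slc35b4, a nucleotide sugar transporter, at -1.49 (SE 0.28), and Atp8b5, a phospholipid flippase, at -1.04 (SE 0.20). None of these passed the test over all genes, with adjusted p between 0.295 and 0.435. By limma 0 of 14620 genes passed, with 919 at an unadjusted p under 0.05 against 731 from chance, 508 of them higher and 411 lower in KO, but the count was 705 with only the arrays compared and 754 with array weights. KO and WT values did not overlap for 1297 genes or 8.87%, where chance gives 10%.

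Type I interferon-stimulated genes did not pass as a list in KO HSC, which does not exclude a small shift. Their mean signal was 7.44 and 7.46 on the HSC arrays of KO mice 11 and 70, 7.21 on that of KO mouse 2, and 7.21 to 7.29 in WT HSC. Their 51 measured members had a median log2 difference of 0.11 and a mean of 0.13 (adjusted p = 0.454 by camera), and none passed singly. The mean stood at 0.20 without mouse 2 and 0.081 without mouse 70. The ubiquitin-like antiviral protein Isg15 stood at 1.55 (SE 0.45) and the oligoadenylate synthetase-like Oasl2 at 1.59 (SE 0.50), while the mono-ADP-ribosyltransferase Parp12 stood at -1.28 (SE 0.36). The receptors and sensors of that pathway had a median of -0.01 (adjusted p = 0.900). The osmoadaptive targets of NFAT5, which bring in and make organic osmolytes and chaperones, had a median of -0.21 and a mean of -0.26 over 9 members (adjusted p = 0.445), the mean standing at -0.14 without mouse 2. Among them the amino acid transporter Slc38a2 stood at -1.84 (SE 0.63), or -1.08 without the HSC array of KO mouse 2, and the heat shock protein Hspa1a at 0.41 (SE 0.16). Stem cell genes had a median of 0.03 and a mean of -0.01 over 32 members (adjusted p = 0.907), with the endothelial and stem cell receptor Tie1 at 0.55 (SE 0.17) and the adhesion molecule Esam at -0.85 (SE 0.36), or -0.29 without WT mouse 12.

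None of the 30 gene lists passed in KO HSC by camera, and 0 passed with an estimated correlation or by fry, where 7 lists had an unadjusted camera p under 0.05. The smallest adjusted p, 0.160, was shared by 6 lists. These were MHC class II presentation (median 0.35), oxidative phosphorylation (0.20), lymphoid priming (0.19), markers of T and NK cells (0.18), p53 targets (-0.15) and markers of mature neutrophils (-0.99). Adjusted over the list alone, and thus not across the 30 lists, 4 genes passed, each higher in KO. Cyb5b passed among the neighbours of Nfat5 (adjusted p = 0.00127), a list whose median of -0.04 and mean of 0.10 differed in sign. Kif23, a kinesin of cytokinesis, passed among mitosis genes at 1.19 (adjusted p = 0.0174), Nkg7, a cytotoxic granule protein, among T and NK markers at 0.74 (adjusted p = 0.0239), and Ndn, the growth suppressor necdin, among quiescence genes at 0.98 (adjusted p = 0.0441). Without mouse 12 the MHC class II and oxidative phosphorylation lists passed by camera (adjusted p = 0.0417 each, and adjusted p = 0.444 each with an estimated correlation). The neutrophil markers did so without mouse 11 (median -1.71, adjusted p = 5.0e-04, and adjusted p = 0.538 with an estimated correlation) and without mouse 64 (median -1.54, adjusted p = 2.7e-04, and adjusted p = 0.905 with an estimated correlation). Without mouse 11, 1 gene passed, Epn1, an endocytic adaptor chosen for naming after its value was seen.

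The same comparison in MPP asked what NFAT5 loss changes once cells have left the stem cell gate. Mitosis genes fell as a list in KO MPP, with a median log2 difference of -0.21 and 25 of 28 members below 0 (adjusted p = 0.00982 by camera). The call was lost with an estimated correlation (adjusted p = 0.700 with an estimated correlation) and by fry (adjusted p = 0.842). Their mean level was 8.30 ± 0.15 in KO and 8.59 ± 0.041 in WT MPP (SD, n = 3). No member passed singly, and those with the lowest p included the spindle kinesin Kif2c at -1.96 (SE 0.89), the kinetochore protein Nuf2 at -0.64 (SE 0.37), the kinetochore kinesin Cenpe at -0.41 (SE 0.22), which stood at -0.19 without KO mouse 70, and cyclin Ccnb2 at -0.28 (SE 0.14). DNA replication genes, the other proliferation list, had a median of -0.06 (adjusted p = 0.703). The mitosis call also ended without WT mouse 12 (adjusted p = 0.0569), without WT mouse 64 (adjusted p = 0.145) and without KO mouse 70 (adjusted p = 0.260).

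**Figure D2:**
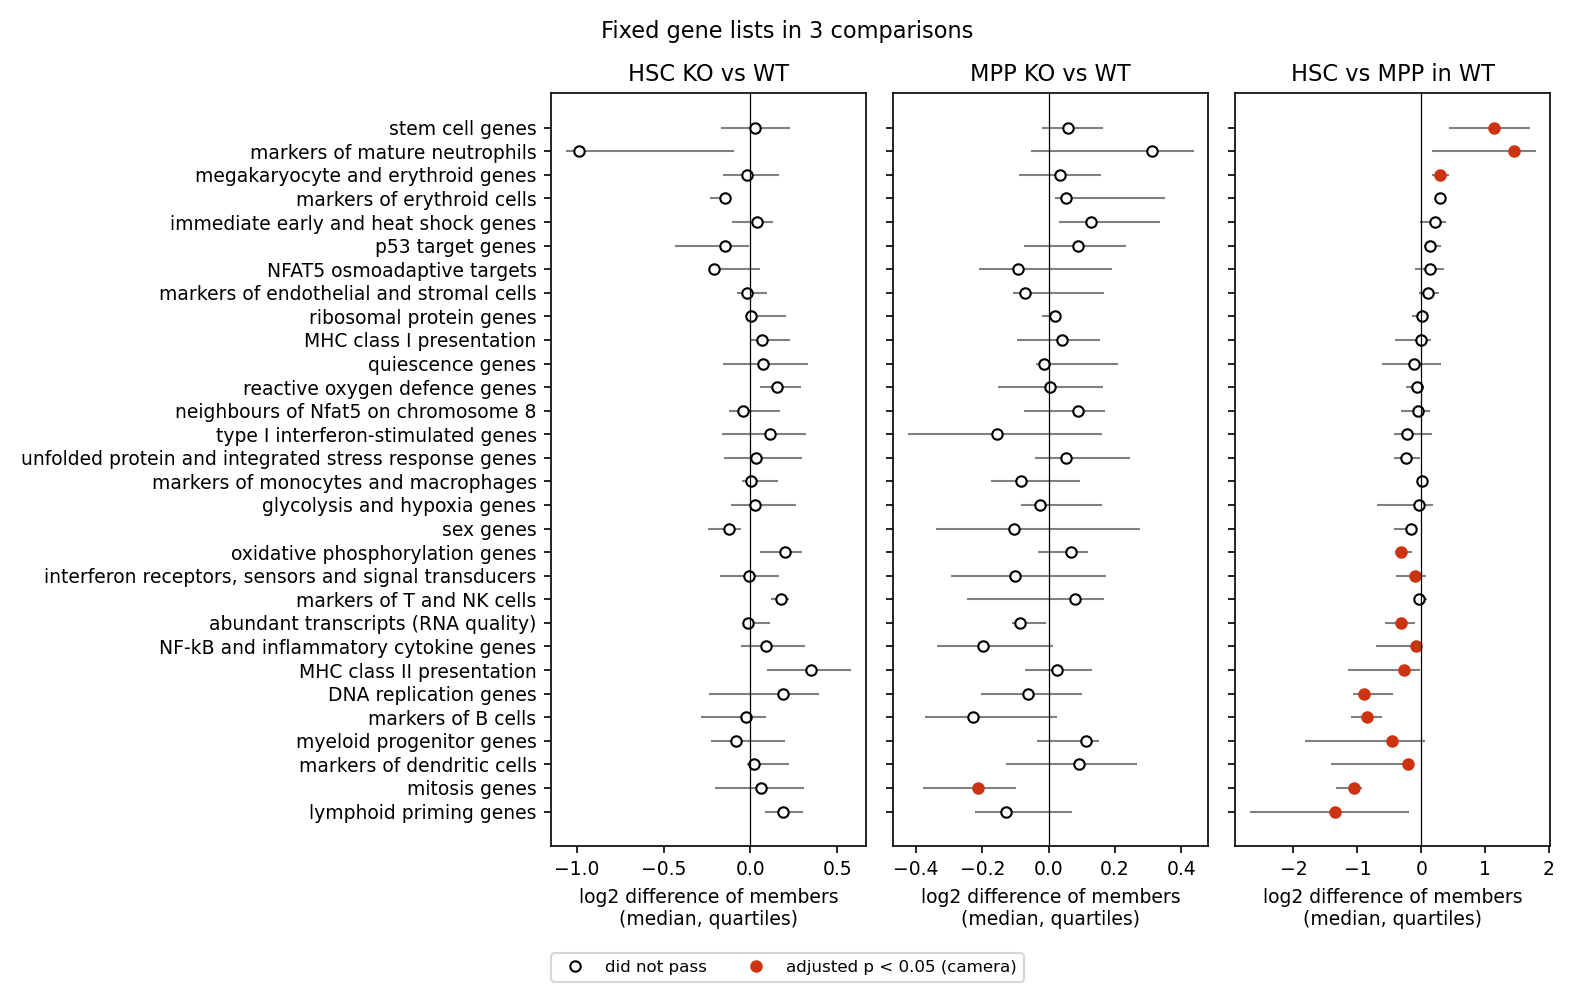
Median (points) and quartiles (lines) of the log2 differences of each gene list's members in KO against WT HSC, KO against WT MPP and WT HSC against WT MPP, with lists that passed camera at the preset correlation in red and with a different horizontal scale in each panel. By that test 0, 1 and 14 of 30 lists passed, of which 0, 0 and 9 also passed with an estimated correlation.

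Single genes in KO MPP stood apart without passing. The sialic acid hydroxylase Cmah was at -1.11 (SE 0.17) and the sialyltransferase St3gal6 at -2.14 (SE 0.44). The complement regulator Cd55 read 7.80 ± 0.84 in KO and 5.05 ± 0.65 in WT (SD, n = 3), a difference of 2.75. Positive differences were also those of Tgif2, a repressor of TGF-beta signalling, at 1.97 (SE 0.36), Zfp57, a zinc finger protein of imprinted loci, at 2.14 (SE 0.49), Gstt2, a glutathione transferase, at 1.53 (SE 0.31), and Fam180a at 0.59 (SE 0.13). Negative ones were those of the T cell costimulator Icos at -0.70 (SE 0.15), the ubiquitin ligase Herc3 at -0.90 (SE 0.20) and the photoreceptor membrane protein Rom1 at -0.65 (SE 0.14). The smallest adjusted p was 0.854, for Cmah. By limma 0 genes passed, with 466 at an unadjusted p under 0.05, fewer than the 731 that chance gives. The count was 652 with only the arrays compared and 716 with array weights. KO and WT values did not overlap for 1387 genes or 9.49% (chance gives 10%). Interferon-stimulated genes had a median of -0.16 (adjusted p = 0.429), with the RNA sensor Ifih1 at -0.80 (SE 0.29), and Stat2, a transducer of the interferon receptor, at -0.61 (SE 0.24), while Slfn5, an interferon-inducible Schlafen protein, went the other way by more than either, with 8.25 ± 0.32 in KO and 7.25 ± 0.37 in WT (SD, n = 3). The osmoadaptive targets had a median of -0.09 and a mean of -0.04, while camera placed them above other genes (adjusted p = 0.987). Adjusted over the list alone, and thus not across lists, 1 gene passed, the endothelial sialomucin Emcn at -1.26 among endothelial and stromal markers (adjusted p = 0.0235).

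With the mouse as the unit, the mean of both populations gave 0 genes by limma, with 650 at an unadjusted p under 0.05 and a smallest adjusted p of 0.897. Nfat5 had the lowest p of that comparison, at -0.89 (SE 0.13). Next to it in the fixed lists stood Oasl2 at 0.84 (SE 0.15) and Cyb5b at 0.78 (SE 0.15), both with an adjusted p of 0.989. Ndn stood at 0.64 (SE 0.19) and Ifih1 at -0.56 (SE 0.17).

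Whether the genotype difference itself differed between HSC and MPP was tested as an interaction, in which positive values mean a higher KO to WT difference in HSC. By limma 0 genes passed, with 658 at an unadjusted p under 0.05 and a smallest adjusted p of 0.884. Isg15 stood at 2.29 (SE 0.64), Parp12 at -2.05 (SE 0.51), Kif23 at 1.30 (SE 0.35) and Nkg7 at 1.08 (SE 0.29). Nfat5 stood at -0.04 (SE 0.33), and between -0.34 and 0.28 when a mouse was left out. Adjusted over the list alone, and thus not across lists, 1 gene passed, Nkg7 among T and NK markers. None of the 30 lists passed, and 7 had an unadjusted camera p under 0.05. The smallest adjusted p was 0.0716, shared by mitosis genes (median 0.27), lymphoid priming genes (0.23), NF-kB and inflammatory cytokine genes (0.38) and p53 targets (-0.23), followed by interferon-stimulated genes (0.26), neutrophil markers (-1.24) and erythroid markers (-0.30), each with an adjusted p of 0.0886. With the mouse as a block 2 lists passed, mitosis genes upward and neutrophil markers downward (adjusted p = 0.0347 each), and both calls were lost with an estimated correlation (adjusted p = 0.566 with an estimated correlation for each). Without the HSC array of KO mouse 2, left out after its spread was seen, 4 passed, namely mitosis genes (adjusted p = 0.0172) and interferon-stimulated genes (adjusted p = 0.0192) upward, and p53 targets and erythroid markers downward (adjusted p = 0.0404 each). These 4 calls were also lost (adjusted p = 0.409, 0.167, 0.247 and 0.247 with an estimated correlation, in that order).

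Other settings gained interaction lists at the preset correlation, and 0 lists passed under any of them with an estimated correlation by camera, where 2 to 4 had an unadjusted p under 0.05. Mitosis genes passed upward with array weights (adjusted p = 0.0323, and adjusted p = 0.294 with an estimated correlation), with the neutrophil marker mean as a covariate (adjusted p = 0.0214, and adjusted p = 0.301 with an estimated correlation), without mouse 2 (adjusted p = 0.00364, and adjusted p = 0.353 with an estimated correlation) and without mouse 3 (adjusted p = 0.0187, and adjusted p = 0.538 with an estimated correlation). The p53 targets passed downward with array weights (adjusted p = 0.0338, and adjusted p = 0.294 with an estimated correlation) and without mouse 3 (adjusted p = 0.00520, and adjusted p = 0.211 with an estimated correlation). Without mouse 3 the NF-kB and inflammatory cytokine genes (adjusted p = 0.0402, and adjusted p = 0.538 with an estimated correlation) and the lymphoid priming genes (adjusted p = 0.0168, and adjusted p = 0.419 with an estimated correlation) passed upward. Interferon-stimulated genes passed upward without mouse 2 (adjusted p = 0.0167, and adjusted p = 0.216 with an estimated correlation), and neutrophil markers downward without mouse 11 (adjusted p = 0.00660, and adjusted p = 0.633 with an estimated correlation).

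**Figure D3:**
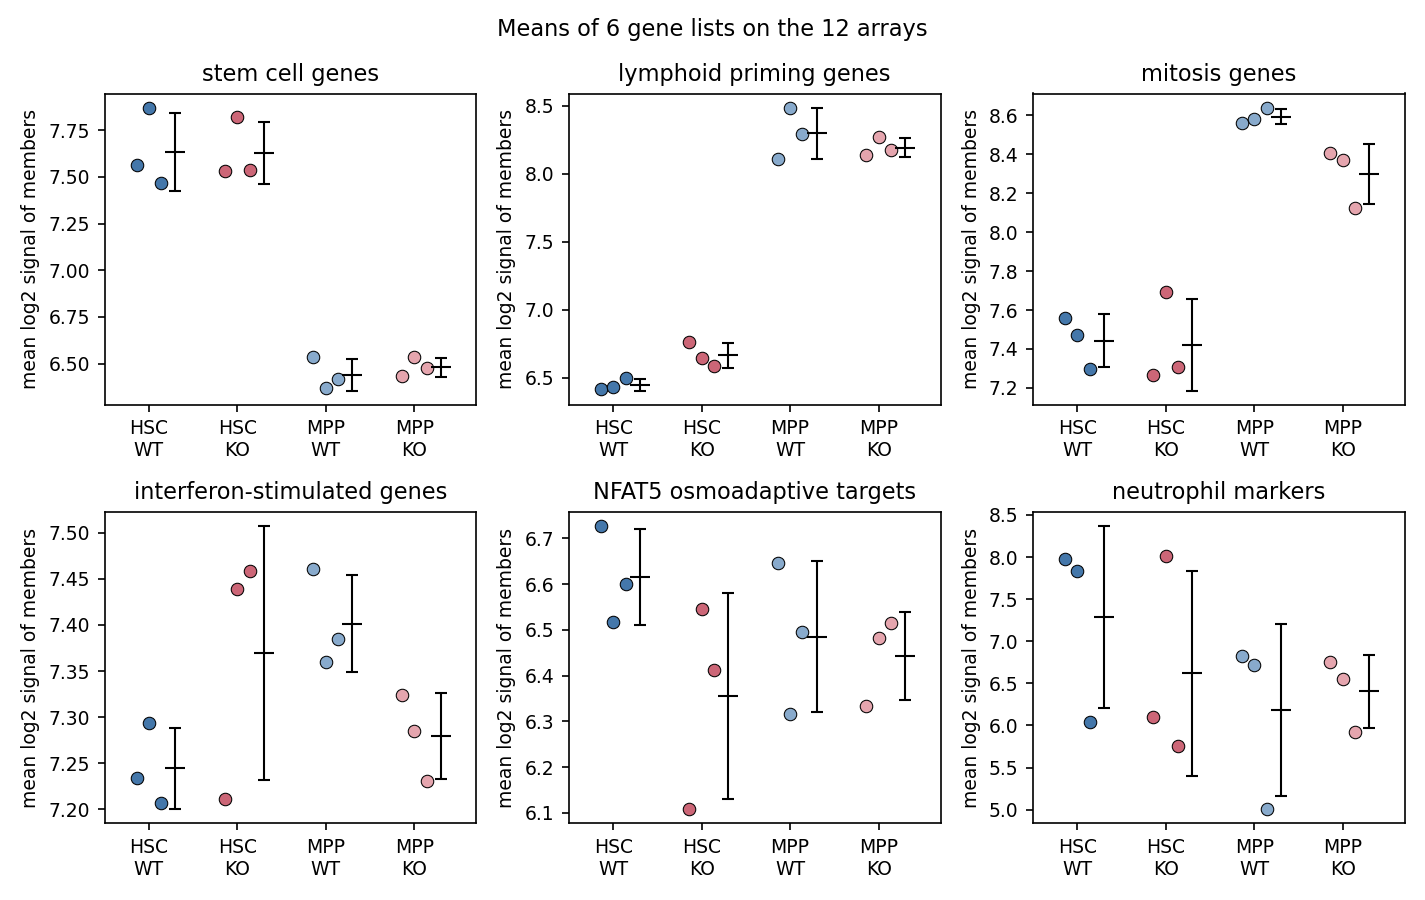
Mean log2 signal of the members of 6 gene lists on each of the 12 arrays (points), by population and genotype, with the group mean and SD beside the points (n = 3) and with a vertical scale of its own in each panel. Stem cell genes averaged 7.63 in WT and 7.63 in KO HSC against 6.44 in WT and 6.48 in KO MPP, and neutrophil markers spread from 5.75 to 8.01 over the 6 HSC arrays.

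The comparison of HSC with MPP in WT mice asked how both populations differ when NFAT5 is present. HSC were low in lymphoid and cell cycle transcripts and high in stem cell transcripts. Dntt, the terminal transferase of lymphoid precursors, read 3.63 ± 0.054 in HSC and 11.53 ± 0.065 in MPP (SD, n = 3), and thus fell by 7.90 on the log2 scale (SE 0.18, adjusted p = 3.3e-09 by limma). The fall can be larger, since its HSC signal lay under 4.96, the value below which genes were left out, and was not shown to be above background. The cytokine receptor Flt3 fell by 3.80 and the chromatin organiser Satb1 by 3.62. Clec1a, a C-type lectin, was higher in HSC by 2.95 and Pdzk1ip1, a small membrane protein of stem cells, by 3.07. By limma 302 genes passed, 109 higher and 193 lower in HSC. The sort genes were not findings, with Slamf1, which encodes CD150, 2.24 higher and Cd48 at -2.82.

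The largest rises in WT HSC were those of Cd55 (3.72), the actin nucleator Spire1 (3.43), the ABC transporter Abcg3 (3.35), Plxdc2 (3.25), the stress-induced chromatin protein Nupr1 (3.25), Ccdc136 (3.13), Pdzk1ip1 (3.07), the neutral amino acid transporter Slc6a15 (2.97), Clec1a (2.95) and Clca3a1 (2.95), with adjusted p between 9.6e-05 for Abcg3 and 0.032 for Ccdc136. The largest falls beside Dntt were those of the flippase Atp8b4 (-4.75), Bex6 (-4.48), the single-stranded RNA sensor Tlr7 (-4.43), Tespa1 of T cell receptor signalling (-4.36), the tetraspanin Cd53 (-3.82), Flt3 (-3.80), the inhibitory myeloid lectin Clec12a (-3.78), Satb1 (-3.62) and the Toll-like receptor homologue Cd180 (-3.57), with adjusted p up to 0.020. For 39 of the 302 genes the lower group mean lay under 4.96, among them Ccdc136, Slc6a15, Clec1a, Dntt, Tlr7, Tespa1, Clec12a, Il7r, Ccr2 and Ccr9. Where that low signal is background, their differences are too small, and their ranks are uncertain. The value 4.96 is no detection limit, and the error of 3 arrays remains, with Ccdc136 at 2.74 without mouse 12. The HSC and MPP values of all 302 genes did not overlap, and this held for 3115 genes or 21.3% of those tested, where chance gives 10%. With the mouse as a block 180 genes passed, 154 of them among the 302, and the calls of Spire1 (adjusted p = 0.0566), Nupr1 (adjusted p = 0.0529), Ccdc136 (adjusted p = 0.0536) and Pdzk1ip1 (adjusted p = 0.0517) were lost. Of the 20 largest calls 9 were lost in some setting, which adds Cd55, Slc6a15, Clec1a, Satb1 and Cd180, each lost without 1 or more mice. Of 62 genes that passed in WT among those chosen by the naming rule or in gene families, the block kept 38, and Pf4, Car2, Mcm5, Vpreb1, Blnk, Ifngr2, Samd9l, Ndn, Cdkn2c and Ccr2 were among the 24 lost. The count was 82 without mouse 3, 96 without mouse 12 and 70 without mouse 64.

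Stem cell genes rose as a list in WT HSC, with a median of 1.15 and 31 of 32 members above 0 (adjusted p = 6.7e-19). Of these members 10 passed over all genes and 19 when adjusted over the list alone, among them Mllt3, a cofactor of stem cell maintenance, at 2.81. Megakaryocyte and erythroid genes rose by a median of 0.30 over 21 members (adjusted p = 0.00101), with the platelet chemokine Pf4 at 1.81 and carbonic anhydrase Car2 at 0.78 higher and the transferrin receptor Tfrc lower at -1.71, which were also the 3 that passed when adjusted over the list alone. Lymphoid priming genes fell by a median of -1.35 over 14 members (adjusted p = 4.8e-13), and 8 were lower by either adjustment, over all genes or adjusted over the list alone, among them the interleukin 7 receptor Il7r at -2.77. Mitosis genes fell by a median of -1.05, with all 28 members below 0 (adjusted p = 6.1e-19), of which 6 passed and 21 when adjusted over the list alone, such as Kif23 at -2.19, topoisomerase Top2a at -1.78 and Ccnb2 at -1.03. DNA replication genes fell by a median of -0.90 over 24 members (adjusted p = 2.5e-12), with 2 and 13 passing in the same order, the helicase subunit Mcm5 at -1.63 and the maintenance methylation factor Uhrf1 at -1.21 being those over all genes. Myeloid progenitor genes fell by a median of -0.45 (adjusted p = 1.7e-06), and 4 of 24 members were lower, 8 when adjusted over the list alone, including the interleukin 1 receptor Il1r1 at -2.58, the sialomucin Cd34 at -2.06 and the sort gene Cd48. B cell markers fell by a median of -0.85 over 8 members (adjusted p = 1.8e-05), with 2 lower and 5 when adjusted over the list alone, those over all genes being the surrogate light chain Vpreb1, at 6.73 ± 0.31 in HSC and 8.73 ± 0.24 in MPP (SD, n = 3), and the adaptor Blnk at -1.37. Oxidative phosphorylation genes fell by a median of -0.31 over 24 members (adjusted p = 1.4e-04), with 0 passing singly by limma or when adjusted over the list alone. Interferon receptors, sensors and signal transducers fell by a median of -0.10 over 22 members (adjusted p = 0.0107), with 2 lower and 5 when adjusted over the list alone, Tlr7 and the interferon gamma receptor chain Ifngr2 at -1.28. Their mean level lay further apart than that median, at 7.02 in HSC and 7.42 in MPP. Tlr7, at -4.43, weighs on that mean, so the call need not hold for most members. These 9 lists also passed with an estimated correlation, with adjusted p from 0.00172 to 0.0438. With the mouse as a block besides, only stem cell, lymphoid priming, DNA replication and mitosis genes did (adjusted p from 0.0252 to 0.0302).

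Another 5 lists passed in WT by camera and were lost with an estimated correlation. MHC class II presentation fell by a median of -0.27 (adjusted p = 0.00791, and adjusted p = 0.139 with an estimated correlation), with H2-Ob, a chain of the peptide-loading modulator, at -2.27. Dendritic cell markers fell by a median of -0.21 (adjusted p = 0.0107, and adjusted p = 0.0537 with an estimated correlation), with Flt3 and the chemokine receptor Ccr9 at -1.80 passing. Both also belong to the lymphoid priming list, so the dendritic call is not a separate result. NF-kB and inflammatory cytokine genes fell by a median of -0.08 (adjusted p = 0.0197, and adjusted p = 0.0677 with an estimated correlation), with the activation antigen Cd69 at -2.92. Abundant transcripts, listed as a sign of RNA quality, fell by a median of -0.32 over 6 members (adjusted p = 0.0197, and adjusted p = 0.321 with an estimated correlation). Among them Tubb5 read 9.80 in HSC and 11.03 in MPP, and Actb 10.81 and 11.22. Between 2 cell populations a difference in RNA quality cannot be told here from a difference in expression of these genes. Markers of mature neutrophils rose in HSC by a median of 1.46 over 11 members (adjusted p = 0.0456, and adjusted p = 0.505 with an estimated correlation), with 0 members passing. Adjusted over the list alone, 2, 2, 3, 0 and 0 members of these lists passed, in that order.

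The remaining 16 lists did not pass between WT HSC and MPP. Interferon-stimulated genes had a median of -0.22 (adjusted p = 0.190), with Samd9l, an antiviral growth inhibitor, 0.78 higher in HSC as the 1 member that passed by either adjustment. Quiescence genes had a median of -0.12 (adjusted p = 0.497), with Ndn higher by 1.19 and the cell cycle inhibitor Cdkn2c lower at -1.81. The NFAT5 targets stood at a median of 0.13 (adjusted p = 0.484), p53 targets at 0.14 (adjusted p = 0.214), unfolded protein and integrated stress response genes at -0.23 (adjusted p = 0.209), immediate early and heat shock genes at 0.22 (adjusted p = 0.152) and glycolysis and hypoxia genes at -0.03 (adjusted p = 0.278). Reactive oxygen defence genes stood at -0.06 (adjusted p = 0.284), MHC class I genes at a mean of -0.09 (adjusted p = 0.476), the neighbours of Nfat5 at -0.06 (adjusted p = 0.431) and sex genes at -0.16 (adjusted p = 0.450). Ribosomal protein genes had a median of 0.02 and a mean of -0.05 (adjusted p = 0.662), and monocyte and macrophage markers a median of 0.02 and a mean of -0.25 (adjusted p = 0.663). Erythroid markers stood at 0.30 (adjusted p = 0.200), endothelial and stromal markers at 0.11 (adjusted p = 0.718) and T and NK markers at -0.03 (adjusted p = 0.285). In these last groups Nkg7 was lower in HSC at -2.72 and the monocyte chemokine receptor Ccr2 at -2.69. Adjusted over the list alone, the growth-response factor Egr1 also passed among quiescence genes, though not among immediate early genes, as did the glutathione synthesis enzyme Gclc among oxygen defence genes, Cyb5b among the neighbours of Nfat5 and the receptor Pdgfrb among stromal markers. Cyb5b stood at -0.73 in WT HSC against MPP (SE 0.18, adjusted p = 0.0788 over all genes).

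The same population comparison in KO mice asked how HSC and MPP differ without NFAT5. Dntt again had the largest measured fall in HSC, by 7.26 or more (SE 0.18, and 7.04 without mouse 11), beside Atp8b4 (-4.56), Tespa1 (-4.03), Bex6 (-4.02) and Tlr7 (-3.58). The largest rises were those of the Wnt co-receptor Ryk (4.15), Pdzk1ip1 (3.73), Nupr1 (3.36), Plxdc2 (3.16) and Phldb2, an adaptor of cortical microtubules (3.09). Stem cell transcripts Tek, the angiopoietin receptor, at 2.35 and Ndn at 1.86 were higher, as was Pf4 at 2.41, while Flt3 (-2.90), Il7r (-2.32), the neutrophil protease Ctsg (-3.28) and Vpreb1 (-2.38) were lower. By limma 184 genes passed, 76 higher and 108 lower. For 31 of them, such as Dntt, Tlr7, Il7r, Ryk, Phldb2 and Tek, the lower group mean lay under 4.96, so that these differences are too small where that signal is background. With the mouse as a block 113 passed, 92 of them among the 184, and the call of Nupr1 was lost (adjusted p = 0.0629). Of the 10 largest calls 4 were lost in some setting, the others being Pdzk1ip1 and Phldb2 without 1 or more mice and Plxdc2 with only the arrays compared. Of 38 genes that passed in KO among those chosen in the same way, the block kept 28. The count was 57 without mouse 2, 83 without mouse 11, 86 without mouse 70, 106 without the HSC array of mouse 2 alone and 79 with only the arrays compared.

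In KO mice 11 lists passed. Stem cell genes rose by a median of 0.85 (adjusted p = 1.1e-18), with 9 members passing and 20 when adjusted over the list alone. Mitosis genes fell by a median of -0.82 (adjusted p = 2.9e-14), with 0 members passing by limma over all genes and 18 when adjusted over the list alone. Lymphoid priming genes fell by -1.14 (6 members, and 8 adjusted over the list alone), DNA replication genes by -0.60 (1 and 6), myeloid progenitor genes by -0.60 (5 and 9), B cell markers by -0.55 (1 and 3), dendritic cell markers by -0.36 (2 and 2), oxidative phosphorylation genes by -0.19 (1 and 1) and interferon receptors and sensors by -0.21 (1 and 1), each as a median. These 9 lists also passed with an estimated correlation, with adjusted p from 0.00328 to 0.0481, but the interferon receptor call was lost without mouse 2 (adjusted p = 0.0790) and the oxidative phosphorylation call without mouse 70 (adjusted p = 0.0563). The 1 interferon receptor and sensor gene that passed was Tlr7, at -3.58. With the mouse as a block besides, 5 of the 9 passed, namely stem cell, mitosis, lymphoid priming, DNA replication and myeloid progenitor genes (adjusted p = 0.0246 each). The dendritic cell list shares Flt3 and Ccr9 with the lymphoid priming list, so its call is not a separate result. Megakaryocyte and erythroid genes rose by a median of 0.22 (adjusted p = 0.0376), a call lost with an estimated correlation (adjusted p = 0.150 with an estimated correlation) and with the mouse as a block (adjusted p = 0.0842). Unfolded protein response genes fell by a median of -0.27 (adjusted p = 0.0456, and adjusted p = 0.441 with an estimated correlation), and stood at a mean of -0.07 without the HSC array of mouse 2.

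Of the genes called in each genotype 115 were shared, all with the same sign. Among these 45 were higher in HSC and 70 were lower. Of the 302 genes called in WT 293 had the same sign in KO, and 181 of the 184 called in KO had the same sign in WT. Across all genes, which are not independent replicates, the differences in WT and KO correlated with r = 0.551. The genotypes share no arrays, but the fit over all 12 arrays gives them 1 estimate of spread per gene, which favours the same genes in both. With a fit of its own for each genotype, 240 genes passed in WT and 79 in KO by limma, and 38 were shared, all with the same sign. Cd55 and Ryk lay far from the shared pattern, and the test of the difference passed for neither, with an interaction of -3.48 for Cd55 (adjusted p = 0.884).

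**Figure D4:**
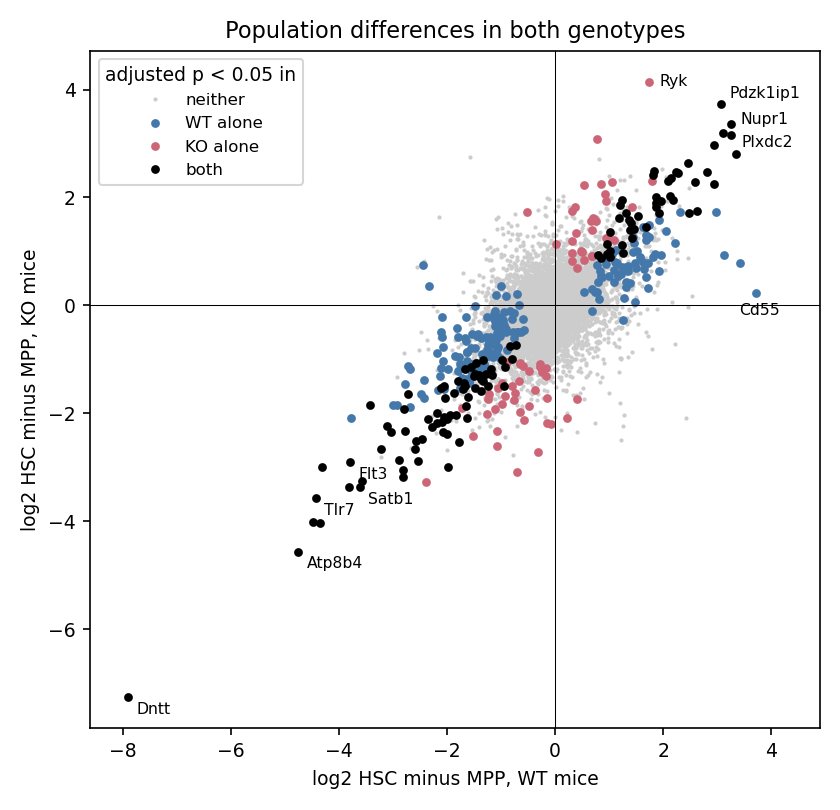
Log2 difference of HSC minus MPP in WT mice (horizontal axis) against KO mice (vertical axis) for the 14620 genes tested, coloured by the genotype in which limma called them. The 115 genes called in both lie at the upper right and lower left, from Dntt at -7.90 and -7.26 to Pdzk1ip1 at 3.07 and 3.73, while Cd55 (3.72 in WT) and Ryk (4.15 in KO) were called in 1 genotype each.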

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

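No test in this part was chosen after a result was seen. Of the 2615 probe sets without a gene name here, 23 passed between HSC and MPP in WT mice, 10 higher and 13 lower in HSC, with a smallest adjusted p of 5.7e-04. In KO mice 16 passed, 4 higher and 12 lower, with a smallest adjusted p of 6.4e-04. None passed between KO and WT mice or in the interaction by limma. What these probe sets measure was not tested.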

How the results depend on the processing

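The fits without the HSC array of KO mouse 2 and with the neutrophil marker mean as a covariate were chosen after the data were seen, and the cause was not tested for any difference between settings. In KO against WT HSC the count of genes was 0 under every setting except without mouse 11, where it was 1, so that it ran from 0 to 1 when a mouse was left out, and the count of lists ran from 0 to 2, reached without mouse 12. In KO against WT MPP the count of lists went from 1 to 0 with an estimated correlation and to 0 by fry, and ran from 0 to 1 when a mouse was left out, the call being lost without mice 12, 64 and 70. The mean of the NFAT5 targets in MPP, -0.04, turned to 0.013 without mouse 2 and 0.038 without mouse 3, and reached -0.13 without mouse 12 and -0.18 with the lowest 50% left out. In the interaction the count of lists went from 0 to 2 with array weights, 2 with the mouse as a block, 4 without the HSC array of KO mouse 2 and 1 with the neutrophil covariate, and ran from 0 to 4 when a mouse was left out, the highest without mouse 3 (NF-kB, lymphoid priming, mitosis and p53 lists), and was 0 under each of these with an estimated correlation, where the smallest adjusted p was 0.167. For HSC against MPP in WT, 302 genes became 180 with the paired block, 187 with the neutrophil covariate, 347 without the HSC array of KO mouse 2 and 399 with array weights, the highest, and 70 without mouse 64 to 297 without mouse 2, while 14 lists became 9 with an estimated correlation. For HSC against MPP in KO, 184 genes became 79 with only the arrays compared, 113 with the block, 106 without the HSC array of KO mouse 2 and 203 with the neutrophil covariate, the highest, and 57 without mouse 2 to 168 without mouse 12. With the block, Spire1, Nupr1, Ccdc136 and Pdzk1ip1 were lost among the largest calls in WT, and Nupr1 (adjusted p = 0.0629) and the megakaryocyte and erythroid list (adjusted p = 0.0842) in KO. With list and family members counted in, the block lost 24 of 62 calls in WT and gained 1, and lost 10 of 38 in KO and gained 2. The immediate early and heat shock list was gained in WT (adjusted p = 0.0366, and adjusted p = 0.286 with an estimated correlation) and the mitosis and neutrophil lists in the interaction (adjusted p = 0.0347), and at the preset correlation the block changed no other list call and no call between KO and WT. With the block and an estimated correlation, 4 lists passed in WT and 5 in KO. These last looks at members, and the estimated correlation under which the interaction lists were lost, were also chosen after the data were seen.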

Other observations

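Gene families, picked by the root of their symbols, and the tests of a wider block around Nfat5, of the splits for Cyb5b, of correlated spread and of 1 mouse for the mitosis list, and of neutrophil RNA and scaling were chosen after the results were seen. Interleukin receptors were lower in HSC than in MPP in both genotypes, by a median of -0.12 over 23 members in WT (adjusted p = 0.00112, and adjusted p = 0.0641 with an estimated correlation) and of -0.45 in KO (adjusted p = 1.6e-06, and adjusted p = 0.00836 with an estimated correlation). In WT 8 members were lower, among them both chains of the interleukin 18 receptor, Il18r1 at -2.07 and Il18rap at -2.10, the interleukin 10 receptor chain Il10rb at -1.78 and the interleukin 17 receptors Il17rb at -1.37 and Il17ra at -1.23. In KO 6 were lower, with Il18r1 at -2.35 and Il10rb at -2.54. The HSC signals of Il18r1 and Il17rb lay under 4.96 in both genotypes, so their differences are too small where that signal is background. Proteasome genes were also lower in HSC than in MPP, in WT by a median of -0.44 over 39 members (adjusted p = 6.5e-06, and adjusted p = 0.0766 with an estimated correlation) and in KO by -0.12 (adjusted p = 0.00919, adjusted p = 0.246 with an estimated correlation, and adjusted p = 0.121 after a second quantile normalization).

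Hox genes rose in WT HSC against WT MPP by a median of 0.21 over 24 members (adjusted p = 0.0117, adjusted p = 0.110 with an estimated correlation, and adjusted p = 0.0835 after a second quantile normalization), with 0 members passing singly by limma. Chemokine receptors fell in KO HSC against KO MPP by a median of -0.07 (adjusted p = 0.0101, and adjusted p = 0.0892 with an estimated correlation). In WT HSC against WT MPP their median was -0.03 (adjusted p = 0.108 by camera). Cxcr4, the receptor that holds stem cells in the marrow, stood at -1.40 in KO, a call lost with the mouse as a block (adjusted p = 0.110). It was also called in WT, at -1.34, and its mean in HSC was 8.09 in KO and 7.84 in WT. Kinesins fell in WT HSC by a median of -0.06 (adjusted p = 0.0495, adjusted p = 0.138 with an estimated correlation, and adjusted p = 0.0579 after a second quantile normalization). Their mean was -0.42, and the 2 members called were Kif23 at -2.19 and Kif4 at -2.68. The family shares kinesins such as Kif23 with the mitosis list, so its call is not a separate result. C-type lectins, with a median of -0.13 in WT HSC, did not pass (adjusted p = 0.0658, and adjusted p = 0.138 with an estimated correlation) but did after a second quantile normalization (adjusted p = 0.0324). The drug efflux transporter Abcg2 was higher in WT HSC at 1.63, and its call was lost with the block (adjusted p = 0.0813), as were those of Il17rb (adjusted p = 0.0796) and Il18rap (adjusted p = 0.0787). Between KO and WT 0 of the 15 families passed by camera in either population, with 1 and 2 at an unadjusted p under 0.05 and smallest adjusted p of 0.339 in HSC and 0.142 in MPP.

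Cyb5b, the protein-coding gene next to Nfat5, read higher in KO arrays of both populations, by 1.16 in HSC and 0.40 in MPP, though between KO and WT it passed only when adjusted over the list alone, in HSC (adjusted p = 0.00127) and for the mean of both populations (adjusted p = 0.0295). A change in most of the other 20 neighbours was argued against, because their median absolute difference was 0.16, at the 14.6th percentile of matched random lists. A block of a few genes would hardly move that median, so the test does not exclude it. Nqo1, on the other side of Nfat5, stood at -0.09 in HSC and 0.11 in MPP (SE 0.21 each). Terf2, beyond Cyb5b, stood at 0.30 and 0.09 (SE 0.35 each). Over the 10 splits of the 6 mice, the absolute t of Cyb5b was 5.13 for the genotypes and at most 1.60 for another split, and 10 splits are too few for a share under 0.05. Cyb5b was taken up for its low p between these same genotypes, so this contrast is no separate evidence. An effect of the edited locus on Cyb5b or a few genes could not be told from a linked difference in strain background or an effect of lost NFAT5. None of these was tested.

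The mitosis list read lower in KO than in WT MPP. Spread shared by its genes between arrays stayed open, with an adjusted p of 0.700 when the correlation between genes was estimated at 0.0563. That test was first set on the unadjusted p, 0.0341, and was moved to the adjusted p after this value was seen. A single mouse was argued against as the source of the mean difference, since 70.3% of it was left without mouse 70. The call by camera did depend on single mice. It was lost without mouse 12 (adjusted p = 0.0569), mouse 64 (adjusted p = 0.145) or mouse 70 (adjusted p = 0.260). The list p by camera was 3.3e-04 for the genotypes and at least 0.0104 for the other splits, and 10 splits are too few for a share under 0.05. The list was taken up because it passed between these same genotypes, so this contrast is no separate evidence.

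Markers of mature neutrophils averaged 7.84 to 8.01 on the HSC arrays of mice 3, 11 and 12 and 5.75 to 6.10 on those of mice 2, 64 and 70, in both genotypes, and on MPP arrays 5.01 and 5.92 for mice 64 and 70 against 6.55 to 6.82 for the other mice. Among them S100a8 read from 6.16 to 10.7 on HSC arrays, S100a9 from 8.20 to 10.9, Ngp from 5.44 to 10.1 and Camp from 5.18 to 9.14. RNA of mature neutrophils that passed the lineage-negative, Sca-1 and Kit positive gate, which would remove them, is a hypothesis left open: the 11 markers, 0 of them in another list, had a mean Spearman correlation of 0.516 over the HSC arrays, at percentile 100 of matched random lists, but a mean that spreads this far requires such a correlation, so the value does not tell sources apart. Granule genes of early myeloid progenitors stayed open too, since Mpo, Elane, Prtn3 and Ctsg correlated with the markers at percentile 99.8. Between populations Mpo and Ctsg did not go with the markers. Mpo read 5.91 to 9.49 on HSC and 10.34 to 10.98 on MPP arrays, and Ctsg 4.28 to 6.88 and 8.18 to 9.78. The marker mean reached 8.01 on HSC arrays but only 6.82 on MPP arrays. This argues against high Mpo and Ctsg signal being enough for high markers. Elane and Prtn3 values overlapped between the populations. A second quantile normalization left 101.5% of the SD. RMA had already set the arrays to 1 distribution, so that test could hardly have come out otherwise and does not decide on scaling. Array means differed by at most 0.0379 after RMA, so any shift of whole arrays left in these values is too small for this spread. RMA makes such means alike, so they do not show whether arrays differed before it. Other distortions between arrays were not tested.

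Splits of the 6 samples into 3 and 3 give 10 groupings, too few for a share under 0.05. The count of genes for the real split and the highest of the others was 0 and 2 in KO against WT HSC, 0 and 0 in MPP, 0 and 0 for the mean of both populations and 0 and 0 in the interaction. It was 302 and 0 for HSC against MPP in WT and 184 and 0 in KO, also against the other splits among the 4 that part all pairs. In these 2 comparisons the other splits mix HSC and MPP arrays within a group. That adds the population difference to the spread and favours a count of 0, so those counts are no fair reference for chance. The counts of lists were 0 and 5 in HSC, 1 and 2 in MPP, where 3 of 10 splits gave as many, 0 and 2 in the interaction, 14 and 8 for HSC against MPP in WT and 11 and 7 in KO.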
